A study of Rattus norvegicus with 24 samples.

How the data were processed

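RNA was measured in the left ventricle of male Wistar rats, taken from the free wall at mid-ventricular level and flash frozen. Per the labels' protocols, total RNA was extracted from the frozen tissue, treated with DNase and depleted of ribosomal RNA. Strand-specific libraries were then made and sequenced as paired ends on a DNBSEQ instrument. The 24 libraries fall into 4 groups of 6 by the treatment and collection time given in the labels. These are a sham group (the dura was opened at a high thoracic level without injury to the cord, and tissue was collected 7 days after surgery) and 3 groups with complete transection of the spinal cord at a high thoracic level (spinal cord injury, SCI), collected 1 day, 3 days or 12 weeks after surgery. The design text gives 6 samples per group, and no label says in so many words that each library came from a different rat. If some did not, the p-values measure only the spread between these samples, part of which would be technical.

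The values used are raw counts per gene, deposited by the authors as 1 table over all 24 libraries, which the labels name as a table of protein-coding genes. Per the submitters' processing notes, FastQC 0.12.1, STAR 2.7.11a and featureCounts 2.0.6 were used with the rat genome build mRatBN7.2. The strand setting of the counting, the annotation release and the treatment of reads that map to several genes are not given in the sources used here. Overlapping or antisense genes and near-identical gene copies may therefore share reads, and which genes these are cannot be listed without names. The table has 26166 lines for 23098 Ensembl gene IDs. A total of 781 IDs appear on more than 1 line, on up to 22 lines each, and all lines of an ID hold identical counts, so each ID was used once. No line lacked an ID. Among the 23098 IDs, 2772 had no count in any library.

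The table gives gene IDs without gene names. The gene table used for names (assembly GRCr8) had an empty column of Ensembl IDs, so that none of the 23098 IDs could be matched, whatever the assembly. No gene is therefore named here, and no coordinates are given. Gene lists and a rule for naming genes had been fixed before the data were examined. Both need gene symbols, so the list tests and the named genes were not run. In their place, genes are described as groups by time and direction, and 4 IDs are printed, 2 that rose and 2 that fell. They were picked by the size part of the fixed rule without its symbol condition. For the comparisons of 1 day and of 12 weeks with sham, each printed ID had the largest rise or fall in log2 fold change among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, and all 6 SCI libraries on the same side of the sham mean. This restriction, and the use of the earliest and the latest time, were chosen after the values were seen.

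Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with enough counts were kept with filterByExpr by group, which left 15065 genes for testing. Libraries were scaled with TMM factors, and all 24 libraries entered 1 model with a term per group and no covariate, with 20 residual degrees of freedom. Each comparison was a contrast tested with the quasi-likelihood F test, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes. A gene is called when its adjusted p is under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Expression levels are given as CPM, the counts scaled by the TMM-adjusted library size. The common biological coefficient of variation was 0.169. Single values per library, such as principal component scores and depth, were compared with two-sided exact permutation tests of the difference of means over all 924 arrangements, adjusted over the 30 tests of that family. The smallest p these can give is 0.00216.

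The depth was 15002476 to 70340174 counts per library, with 16087 to 17782 genes detected. In every library even numbers made up 58.1 to 61.1% of the gene counts between 1 and 200, so a count may not stand for 1 independent RNA fragment. Replicates were compared with a chi-square test of their counts. Over the 60 pairs within groups, chi-square per degree of freedom lay between 12.6 and 108.6, far above sampling noise. No library was therefore a second sequencing of another library in its own group. A second library made from the same tissue or rat could also exceed sampling noise and is not excluded. Pairs across groups were not compared in this way. The steps were tested on 1 set of simulated counts per comparison, drawn from the real sham means, the fitted dispersions and each library's own size, with 200 changed genes among the 15065. For 1 day against sham, 64.6% of the genes changed 1.5-fold, 86.4% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 14 of 182 calls were false. For 3 days the shares were 52.9%, 78.9% and 93.2% with 11 of 161 calls false, and for 12 weeks 70.3%, 77.3% and 98.6% with 9 of 174 calls false. Each gene had the same simulated dispersion in all groups. In the real libraries the biological coefficient of variation per group was 0.124 in sham and 0.153, 0.177 and 0.214 in the SCI groups in order of time. The simulated shares therefore do not tell how the test does on groups of unequal spread.

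The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper quartile factors, no low-count filter, a filter of a CPM of at least 1 in 6 libraries, limma-voom with sample weights (limma 3.58.1), a fit of only the 2 groups compared, the replicate number as a block, surrogate variables (sva 3.50.0, which found 5), and leaving out each library in turn. For overlaps, an adjusted p under 0.01, a 2-fold threshold and splits of the sham libraries were also fixed. Alternatives chosen after seeing the data were the removal of 3 libraries that correlated least with their group, the removal of the 10 most abundant genes, all repeated lines kept, counts divided by 2, and splits of the 1 day libraries. The use of any of these alternatives for the groups of genes by time and for the share of 1 day calls that moved back was decided after seeing the data. The same holds for the overlaps, apart from DESeq2, the thresholds and the split sham libraries.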

Results

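The study asked how a high thoracic spinal cord injury changes gene expression in the heart. RNA levels of genes were measured in the left ventricle of rats after sham surgery and 1 day, 3 days or 12 weeks after complete cord transection, with 6 libraries in each group. Transection at this level cuts the descending nerve pathways that drive the sympathetic supply of the heart. The mean depth was 46931046 ± 16702221 counts per library in the sham group (SD, n = 6), 50110657 ± 8326784 at 1 day, 33413527 ± 11280885 at 3 days and 31402927 ± 9498580 at 12 weeks. The 1 day libraries were deeper than those at 3 days (exact permutation p = 0.0195, adjusted p = 0.0418) and at 12 weeks (exact permutation p = 0.00649, adjusted p = 0.015). No SCI group differed from sham in depth by this test, with exact permutation p-values of 0.682, 0.132 and 0.0736 in order of time. Genes carry only their Ensembl IDs in the deposited table and are described as groups.

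The libraries separated by treatment and by time. On the first principal component, which held 22.1% of the variance, the mean score was 22.1 ± 6.20 at 1 day and 19.4 ± 7.85 at 3 days (SD, n = 6), against -6.14 ± 4.4 in sham and -35.3 ± 15.5 at 12 weeks. The acute and the late SCI groups therefore lay on opposite sides of sham, each apart from it with an exact permutation p of 0.00216 (adjusted p = 0.00589), the smallest the design allows. On the second component, with 12.3% of the variance, sham stood at 28.9 ± 4.35 and the SCI groups at -8.72 ± 2.88, -7.20 ± 13.8 and -13.0 ± 8.07 in order of time, again with an exact permutation p of 0.00216 for each against sham. The scores at 1 and 3 days were not told apart on either component (exact permutation p = 0.543 and 0.877).

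**Figure D1:**
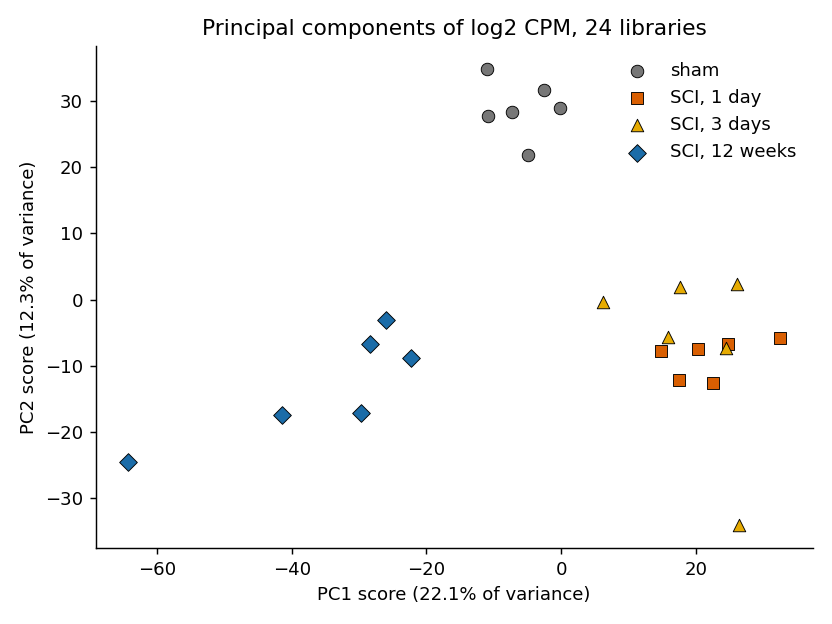
Scores of the 24 libraries on the first (x axis, 22.1% of variance) and second (y axis, 12.3%) principal components of log2 CPM, 1 point per library, coloured by group. Sham libraries lie between 21.9 and 34.9 on the second component, above all SCI libraries, and the 12 week libraries lie at or below -22.3 on the first, while 3 day replicate 5 stands apart at -34.1 on the second.

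At 1 day after transection, 1795 genes were higher and 1820 lower than in sham, together 24% of the 15065 genes tested by edgeR's quasi-likelihood test. Most changes were modest, with a median size of 1.37-fold among called genes. A change of over 2-fold was seen in 304 of the higher and 242 of the lower genes, and one of over 4-fold in 29 and 22. The largest rise among the genes eligible for printing was that of ENSRNOG00000021027, from 6.84 ± 3.51 CPM in sham to 68.6 ± 26.6 CPM at 1 day (SD, n = 6), a log2 fold change of 3.32 (SE 0.349, adjusted p = 6.6e-07). Its log2 fold change was 2.11 at 3 days (adjusted p = 0.000134) and 0.81 at 12 weeks, which was not called (adjusted p = 0.0866). The 12 week value was called without sham replicate 3 (1.14, edgeR adjusted p = 0.0175), without 12 week replicate 5 (0.96, adjusted p = 0.048) and with surrogate variables (1.09, adjusted p = 0.0365). The largest fall was that of ENSRNOG00000014448, from 39.9 ± 16.3 to 4.72 ± 1.25 CPM, a log2 fold change of -3.08 (SE 0.38, adjusted p = 4.66e-06). It was -2.18 at 3 days (adjusted p = 0.000226) and -0.76 at 12 weeks (adjusted p = 0.119), the latter called without sham replicate 3 (-0.94, edgeR adjusted p = 0.0447) and with limma-voom (-0.97, adjusted p = 0.0439). Sham tissue was taken 7 days after surgery, so no SCI group is matched to it in time.

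At 3 days after transection, 1338 genes were higher and 1294 lower than in sham, or 17.5% of those tested. Among them, 209 rose and 149 fell by over 2-fold, and the median size of a called change was again 1.37-fold. The library numbers in the labels run from 57 to 68 for the 3 day and sham groups and from 77 to 88 for the 1 day and 12 week groups. The comparison of 3 days with sham therefore lies within 1 run of numbers, while those of 1 day and 12 weeks with sham do not and have no value within a run.

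The responses at 1 and 3 days overlapped in 1780 genes that changed in the same direction. Of the genes called against sham at both times, 906 were higher and 874 lower at both, where independent lists of these sizes would share 159 and 156. Another 3 were called in opposite directions, against 316 for independent lists. The opposed count was 17 with surrogate variables, 13 with limma-voom, 8 without 3 day replicate 3 or 12 week replicate 3, and 7 without 3 day replicate 5. Their IDs are not printed because the table gives them no names. Both comparisons use the same sham libraries. In 20 simulations with no effect in any group edgeR called no gene at either time, so these give no overlap to set beside the counts. With the sham libraries split between the comparisons a median of 724 genes were shared in direction over 20 arrangements, with 2 opposed. Each comparison then had only 3 sham libraries and so less power. The fall from 1780 therefore does not measure the part of the overlap due to shared sham libraries. The fold changes correlated across genes with r = 0.773 (genes are not independent replicates). Simulated unchanged groups gave r = 0.487 from the shared sham libraries. The covariance was 0.141 against a simulated 0.0203, a difference of 0.121. Each gene had the same simulated dispersion in all groups. In the real libraries the biological coefficient of variation was 0.124 in sham, 0.153 at 1 day and 0.177 at 3 days, so the simulated values need not hold for these groups. With the sham libraries split, the median covariance was 0.135.

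The direct comparison of 3 days with 1 day called 186 genes higher and 227 lower at 3 days, 2.74% of those tested, with a median size of 1.30-fold. The 3 day and 1 day libraries also come from different runs of library numbers, so a difference between runs could give any of these calls. Among the genes raised at 1 day, 120 had fallen back by 3 days. Their median log2 fold change against sham was 0.50 at 1 day and 0.06 at 3 days. Among the genes lowered at 1 day, 107 had risen back, from a median of -0.37 to 0.02. The same 1 day libraries set the call and the later difference, which favours such medians, and no split was run for these genes. At 12 weeks, in the same run of library numbers as 1 day, the medians were 0.215 for the raised and -0.091 for the lowered genes. A difference between runs could also give 12 week medians in these directions. Another 39 genes were higher than sham at 3 days and higher than at 1 day, and 71 were lower than both. These counts rest on few libraries: without 1 day replicate 5 the comparison called 77 genes higher and 93 lower, and without 3 day replicate 5 it called 285 and 328. DESeq2 called 367 and 444, and limma-voom with sample weights 416 and 537. Without 1 day replicate 5 the groups of 120, 107, 39 and 71 genes held 50, 40, 24 and 32, and without 3 day replicate 4 they held 53, 52, 10 and 34. At most, the first pair held 330 and 299 without the 3 least correlated libraries, and the second 109 and 157 with surrogate variables.

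**Figure D2:**
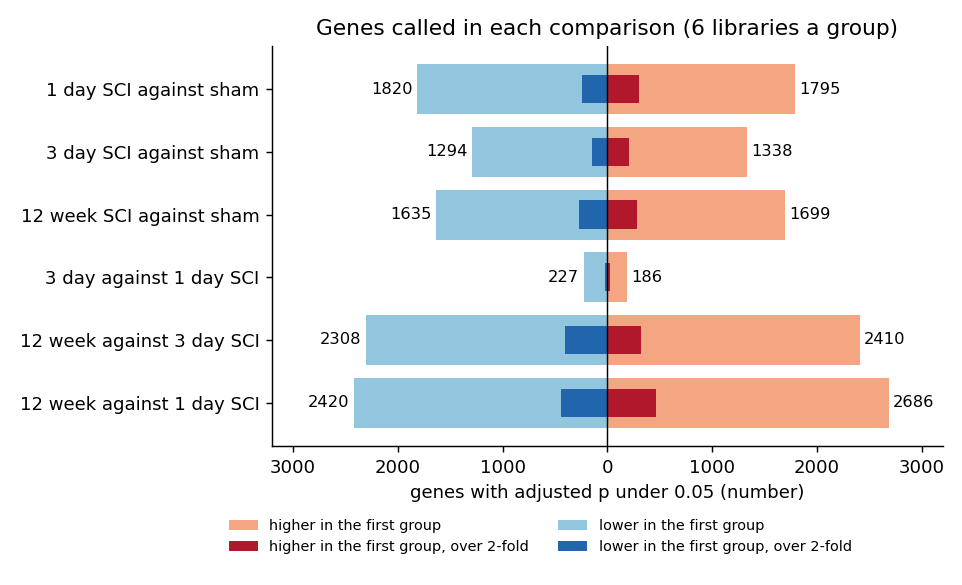
Number of genes called (x axis, adjusted p under 0.05, edgeR) as higher (right) or lower (left) in the first-named group of each of the 6 comparisons (y axis), with the narrow dark bars for changes over 2-fold. The comparison of 3 days with 1 day has the fewest (186 and 227) and that of 12 weeks with 1 day the most (2686 and 2420).

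At 12 weeks after transection, 1699 genes were higher and 1635 lower than in sham, or 22.1% of those tested, and 287 and 273 of these changed by over 2-fold. The count of genes that rose by over 4-fold was 65, against 29 that fell as far. The largest rise among the genes eligible for printing was that of ENSRNOG00000043098, from 4.67 ± 1.74 to 68.7 ± 73.9 CPM (SD, n = 6), a log2 fold change of 3.87 (SE 0.548, adjusted p = 2.96e-05). One library carried much of this mean, since 12 week replicate 3 had 216 CPM and the others 18.4 to 57.3 CPM. Without it the log2 fold change was 3.06, and with all libraries it was 3.24 with limma-voom and 2.84 with surrogate variables. The largest fall was that of ENSRNOG00000020407, from 36.0 ± 14.9 to 2.26 ± 2.29 CPM, a log2 fold change of -3.96 (SE 0.679, adjusted p = 0.000209), and -4.73 without 12 week replicate 2. The main edgeR fit, with all libraries and no covariate, called neither gene at 1 day (log2 fold changes of 1.26 and -0.53) or at 3 days (0.56 and -0.60). The 3 day value of ENSRNOG00000020407 rested on 3 day replicate 5, with 86.1 CPM where the others had 3.09 to 20.2 CPM. Without it the gene was called lower than sham at 3 days too, with a log2 fold change of -1.59 (edgeR adjusted p = 0.0325), as it was with limma-voom (-1.79, adjusted p = 0.0106) and with surrogate variables (-1.42, adjusted p = 0.033). ENSRNOG00000043098 was called higher at 1 day without 1 day replicate 6 (1.47, edgeR adjusted p = 0.0362), with only the 2 groups compared (1.27, adjusted p = 0.0165) and with surrogate variables (1.19, adjusted p = 0.0143). The 12 week rats were also collected much later after surgery than the sham rats, so the difference holds any effect of those weeks as well as that of the injury.

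**Figure D3:**
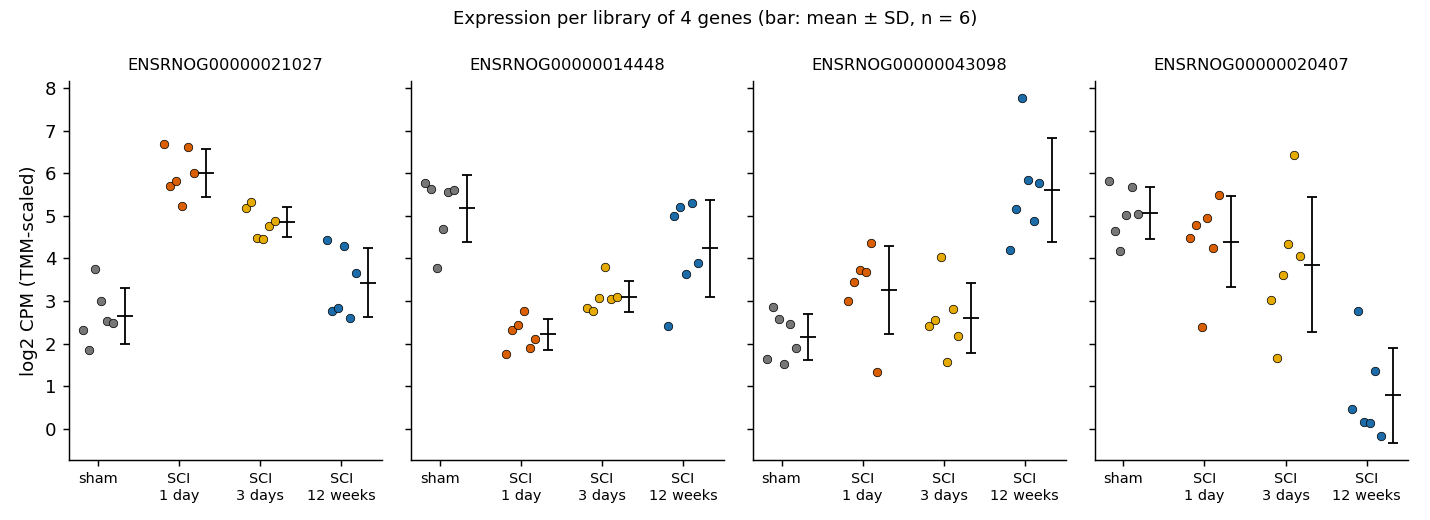
Log2 CPM (y axis, TMM-scaled) of the 4 printed genes in each library, by group (x axis), with the mean ± SD of 6 libraries beside the points. ENSRNOG00000021027 and ENSRNOG00000014448 departed most from sham at 1 day, with log2 fold changes of 3.32 and -3.08, and ENSRNOG00000043098 and ENSRNOG00000020407 at 12 weeks, with 3.87 and -3.96.

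Many genes differed between 12 weeks and the acute times. The direct comparisons called 2686 genes higher and 2420 lower at 12 weeks than at 1 day, and 2410 higher and 2308 lower than at 3 days. A late group of 749 genes was higher at 12 weeks than in sham, than at 1 day and than at 3 days. Their median log2 fold change against sham was 0.43 at 12 weeks, and -0.03 at each of the acute times. A late group of 767 genes was lower than in all of the other groups, with a median of -0.60 at 12 weeks, 0.06 at 1 day and 0.05 at 3 days. Both late groups were picked by tests on the same libraries, so their medians follow in part from the selection. At 12 weeks 145 and 160 members of these groups differed from sham by over 2-fold.

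A transient group behaved the other way. It held 378 genes that were higher than sham at 1 and 3 days and then fell by 12 weeks relative to both, with median log2 fold changes against sham of 0.57, 0.51 and -0.04 in order of time. Its counterpart held 443 genes that were lower at both acute times and then rose, with medians of -0.49, -0.47 and 0.03. Medians close to sham at 12 weeks follow in part from the selection, which used the same libraries. Among all genes raised at 1 day, 52.6% were lower at 12 weeks than at 1 day by test, and among those lowered at 1 day, 56.0% were higher, together 54.3%. The same 1 day libraries set both the call and the later difference, which favours such a return. With the 1 day libraries split between the call and the later difference, the share was 42.0% (36.1 to 49.6% over 20 arrangements). Each step then used only 3 of the 1 day libraries, so lost power may also lower this share. By direction alone, without a test of the later difference, a median of 85.4% of the called genes moved back.

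A sustained group was called against sham at all 3 times in 1 direction, with 302 genes higher and 260 lower. The lower part held 426 genes with limma-voom and 396 with surrogate variables. The median log2 fold changes of the higher genes were 0.70, 0.59 and 0.56 in order of time, and those of the lower genes -0.62, -0.59 and -0.53. For 201 of the higher and 181 of the lower genes no difference between times was called, which does not show that their levels were equal. A further 89 genes were higher than sham at 1 day and lower at 12 weeks, with medians of 0.48 and -0.57, and 86 were lower at 1 day and higher at 12 weeks, with medians of -0.33 and 0.34. These opposed counts fell to 53 without sham replicate 5 and to 51 without sham replicate 1, and rose at most to 150 and 127 with limma-voom.

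Across the comparisons with sham, 6465 genes (42.9%) were called at some time and 8600 at none. Calls at 1 day and 12 weeks overlapped in 491 genes higher at both and 455 lower at both, where independent lists would share 202 and 198, and in 175 opposed, where they would share 400. The 1 day and 12 week libraries share a run of library numbers that sham does not. A difference between runs could therefore add to the genes shared in direction, and this was not tested. Of the shared genes, 302 higher and 260 lower were also called in that direction at 3 days, within the run of sham. Another 189 higher and 194 lower were not called at 3 days. The correlation across genes was 0.332, below the 0.495 that shared sham libraries alone gave in simulations of unchanged groups, and the covariance was 0.0689 against a simulated 0.0209. For 3 days and 12 weeks, 372 genes were higher at both, 331 lower at both and 144 opposed, against 151, 140 and 291 for independent lists. The correlation was 0.338 against a simulated 0.477, and the covariance 0.0651 against 0.0207. A correlation falls when changes at only 1 of the times widen the spread, so observed and simulated correlations are not on 1 scale. The lower correlations therefore do not show less sharing than the sham libraries alone give, and the covariances lay above the simulated ones for both pairs. The simulations gave each gene the same dispersion in all groups, although the spread was smaller in sham than in the SCI groups. With the sham libraries split, a median of 373.5 genes shared a direction and 54 were opposed for 1 day and 12 weeks, with r = 0.227. For 3 days and 12 weeks the counts were 246 and 38, with r = 0.223. The median covariances were 0.0588 and 0.056 in that order. Each comparison then had fewer sham libraries and so less power, and these counts do not measure the part due to shared sham libraries. The same split gave r = 0.573 for 1 and 3 days. The opposed counts moved with single sham libraries and with the method. For 3 days and 12 weeks they were 88 to 95 without any 1 of the 6 sham libraries and 223 with limma-voom, and for 1 day and 12 weeks 109 without sham replicate 5 and 277 with limma-voom.

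**Figure D4:**
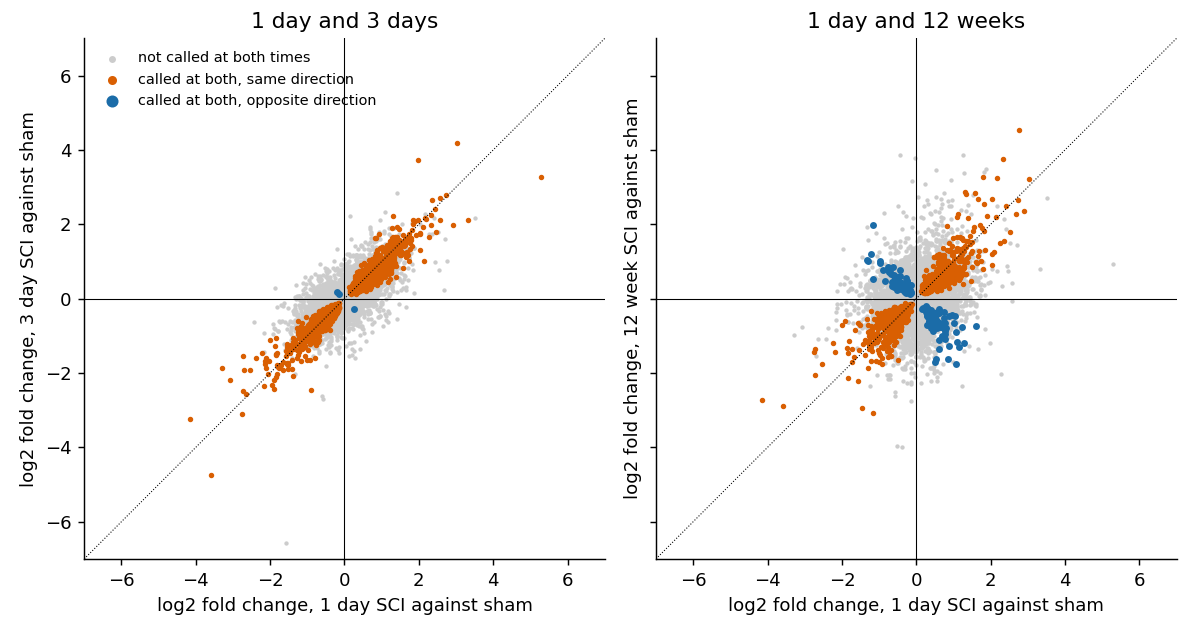
Log2 fold change against sham of each of the 15065 genes at 1 day (x axes) and at 3 days (left, y axis) or 12 weeks (right, y axis), with genes called at both times coloured by whether their directions match and the dotted line marking equal change. At 3 days 1780 genes matched and 3 were opposed, and at 12 weeks 946 matched and 175 were opposed.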

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

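The tests of the library numbers, of mislabelled samples, of even counts and of other splits of the samples were chosen after the results they bear on had been seen. The tests of depth were written down before the libraries were thinned. They name the libraries with low correlation, so those correlations had been seen by then.

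The SCI groups differed from one another by direct test (edgeR, Benjamini-Hochberg), which compares groups and, with no sham at each time, does not show that the effect of the injury differed. The contrasts called 413 genes between 3 days and 1 day, 4718 between 12 weeks and 3 days, and 5106 between 12 weeks and 1 day. Chance was weighed by drawing 100 of the 462 splits of each pair of groups, the real one included, and refitting only those 12 libraries. In each of the 6 comparisons only the real split, 1 of the 100, gave as many calls. Chance is therefore an unlikely source of the counts in these fits, although the splits not drawn were not fitted. Where the groups also differ in their run of library numbers, the splits cannot tell the group from the run. The real and the highest other counts were 4829 and 101 for 1 day against sham, 2869 and 40 for 3 days, 3000 and 5 for 12 weeks, 259 and 18 for 3 days against 1 day, 3280 and 1 for 12 weeks against 3 days, and 4320 and 16 for 12 weeks against 1 day.

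The library numbers, 57 to 68 for the 3 day and sham groups and 77 to 88 for the others, may mark separate rounds of preparation, although no label says so. If such a round were the whole cause of the differences, comparisons within a run of numbers would call few genes. Instead, the comparison of 3 days with sham, within a run, called 6.37 times as many genes as that of 3 days with 1 day, across runs, and that of 12 weeks with 1 day, within a run, 12.4 times as many. Both ratios use the comparison across runs with the fewest calls. The others across runs called 3615 genes for 1 day with sham, 3334 for 12 weeks with sham and 4718 for 12 weeks with 3 days. The ratios therefore depend on this choice, which was made after the results were seen. The 2632 and 5106 calls within runs argue against the numbers as the whole cause. A contribution to the comparisons that cross the runs stays open. These are 1 day and 12 weeks with sham, 3 days with 1 day, and 12 weeks with 3 days. For 3 days with 1 day the runs could give all of the 413 calls. The effects of time after surgery and of age at 12 weeks stay open too and were not tested.

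The median correlation of log2 CPM with the own group was 0.971 in 3 day replicate 5, far below the rest of its group, 0.977 in 12 week replicate 1 and 0.968 in 12 week replicate 3, and 3 day replicate 5 also lay apart on the second principal component, at -34.1. After every library was thinned to 15002476 counts, 3 day replicate 5 stayed low at 0.9738 and 12 week replicate 3 at 0.9682, which argues against depth as the cause, whereas 12 week replicate 1 rose to 0.9802, level with its group, so that depth may account for it. The thinned group means of 0.984 at 1 day, 0.980 at 3 days and 0.979 at 12 weeks were all below the 0.985 of sham, each with an exact permutation p of 0.00216 (adjusted p = 0.00324). The values of a group share their pairs of libraries, and 1 odd library can lower the others, so these p-values overstate the evidence. The lower correlation of the 3 day and 12 week groups remained at equal depth, so depth alone does not account for it. A wider spread between injured rats stays open. The biological coefficient of variation was 0.124 in sham and 0.153, 0.177 and 0.214 in the SCI groups, which describes the same libraries and does not tell its source. With the 1 and 3 day groups joined, 3 of these 3 libraries were closest to their own group, which argues against a mix-up with sham or between acute and late tissue. Whether 3 day replicate 5 is a mislabelled 1 day library cannot be told apart from its given label, since its correlation with the 3 day mean minus that with the 1 day mean was -0.000451, below the 0.000201 of the lowest other 3 day library (mean 0.00141, SD 0.000769) but within 1 SD of 0, yet such a label would not account for its low correlation, since after thinning it correlated with the 1 day mean at 0.9816, against 0.9896 to 0.9908 for the 1 day libraries.

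Even counts outnumbered odd counts in the deposited table. In 24 of 24 libraries more genes had a count of 2 than a count of 1 or a count of 3, in sham replicate 1 for example 790 against 261 and 175. This is consistent with both mates of a read pair having been counted separately, which would make the number of sequenced fragments smaller than the counts. The setting used for counting pairs is not given in the sources used here. No biological explanation was tested.

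Single values also stood out. The median correlation of sham replicate 1 with its group was 0.9884, above the other sham libraries, and the log2 CPM of ENSRNOG00000014448 in 3 day replicate 4 was 3.79, above the other 3 day libraries. In all, 4 of 44 such tests singled out a library, where chance gives about 2.2. The 4 printed genes were also called in edgeR contrasts between times. They had been picked as the extremes of 1 day or 12 weeks, and the contrasts reuse those libraries, which favours a difference. Between 12 weeks and 1 day the log2 difference was -2.51 for ENSRNOG00000021027 (adjusted p = 7.44e-06), 2.32 for ENSRNOG00000014448 (adjusted p = 5.54e-05) and -3.43 for ENSRNOG00000020407 (adjusted p = 0.00039). Between 12 weeks and 3 days it was 3.31 for ENSRNOG00000043098 (adjusted p = 6.59e-05).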

How the results depend on the processing

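The removal of the 3 least correlated libraries or the 10 most abundant genes, repeated lines, halved counts, the split of the 1 day libraries, and all alternatives for the groups of genes by time, for the share that moved back and, other than DESeq2, thresholds and split sham libraries, for the overlaps were tests chosen after the results were seen. The gene list tests, and library sizes without mitochondrial and globin genes, were not run, since the table gives no gene names. The counts of genes higher and lower than sham at 1 day, 3 days and 12 weeks, and those of 12 weeks against the earlier times, stayed within 1.5 times under each alternative run, as did the share of 1 day calls that moved back (54.3%; lowest, with the 1 day libraries split, 42.0%). The called genes changed more than their counts. With surrogate variables 67.9% of the calls of 12 weeks against sham, 66.6% of those against 3 days and 73.4% of those against 1 day were kept, the lowest shares for these comparisons, and for the late groups of 749 and 767 genes 55.3% and 63.5%. With only the 2 groups compared 50.1% of the calls of 3 days against 1 day were kept, and 40% without 1 day replicate 5. For 1 day and 3 days against sham the lowest shares, without sham replicate 2, were 83.2% and 76%. Of the 1096 counts and shares recomputed under an alternative, 981 stayed and 115 moved by over 1.5 times. Of the 300 recomputed log2 fold changes of the 4 printed genes against sham at the 3 times, none changed direction and 286 kept their call, while 14 became called at a time at which the gene had not been. In 9 the fold itself moved by over 1.5 times. The 115 concern 3 days against 1 day, the overlaps and the groups by time, and their cause was not tested except where a stricter threshold or fewer samples gives it.

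For 3 days against 1 day (186 genes higher, 227 lower), DESeq2 called 367 and 444, limma-voom with sample weights 416 and 537, surrogate variables 452 and 565, only the 2 groups compared 119 and 140, and the fit without the 3 least correlated libraries 467 and 551. Leaving out 1 library gave 77 (without 1 day replicate 5) to 285 (without 3 day replicate 5) genes higher and 93 to 328 lower. Genes higher also fell below a 1.5 times lower count without 1 day replicates 1 and 4 (90 and 102) and 3 day replicates 2, 4 and 6 (119, 84 and 118), and genes lower without 1 day replicate 1 (149) and 3 day replicates 2 and 4 (140 and 101).

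Calls shared in direction by 1 and 3 days (1780) numbered 840 at an adjusted p under 0.01, 224 at 2-fold and 724 with sham split; by 1 day and 12 weeks (946), 398, 112 and 373.5, and 1449 with limma-voom; by 3 days and 12 weeks (703), 271, 85 and 246. Opposed calls at 1 and 3 days (3) numbered 7 with DESeq2, 5 with upper quartile factors, 6 with the CPM filter, 13 with limma-voom, 8 with only the 2 groups compared, 17 with surrogate variables, 11 without the 3 libraries, 5 with counts halved, 0 at 2-fold, and 2 to 8 leaving out 1 library (8 without 3 day replicate 3 or 12 week replicate 3, 7 without 3 day replicate 5). Opposed calls at 1 day and 12 weeks (175) numbered 277 with limma-voom, 36 at 0.01, 8 at 2-fold, 54 with sham split, and 109 (without sham replicate 5) to 219 leaving out 1 library. Those at 3 days and 12 weeks (144) numbered 223, 25, 2 and 38 in the same order, and 88 to 166 leaving out 1 library, with 88 to 95 without any 1 of the 6 sham libraries.

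The late groups (749 higher, 767 lower) and the transient groups (378 and 443) stayed within 1.5 times under each alternative run. Leaving out 1 library gave 621 to 795 and 673 to 824 late genes, and 315 to 407 and 341 to 476 transient ones. The sustained groups (302 and 260) held 243 to 377 and 197 to 348 genes leaving out 1 library, and the lower one 426 with limma-voom and 396 with surrogate variables; its part with no difference called between times (181) held 302 and 283. Genes higher at 1 day that fell back by 3 days (120) numbered 227 with DESeq2, 327 with limma-voom, 311 with surrogate variables and 330 without the 3 libraries, and 50 (without 1 day replicate 5) to 195 (without 12 week replicate 3) leaving out 1, with 73 and 69 without 1 day replicates 1 and 4, and 68, 53 and 186 without 3 day replicates 2, 4 and 5. Genes lower that rose back (107) numbered 200, 257, 268 and 299 in the same order, 67 with no filter, and 40 to 181 leaving out 1, with 52 and 66 without 1 day replicates 1 and 4, 63, 52 and 181 without 3 day replicates 2, 4 and 5, and 166 without 12 week replicate 3. Genes higher at 3 days than in sham and at 1 day (39) numbered 88, 105, 109 and 101 in that order, and 10 to 72 leaving out 1, with 20, 17 and 24 without 1 day replicates 1, 4 and 5, 10 and 21 without 3 day replicates 4 and 6, and 72 without 12 week replicate 3. Genes lower than both (71) numbered 118, 152, 157 and 129, 41 with only the 2 groups compared, and 32 to 105 leaving out 1, with 46 and 32 without 1 day replicates 2 and 5, and 41, 34 and 44 without 3 day replicates 2, 4 and 6. Genes higher at 1 day and lower at 12 weeks (89) numbered 150 with limma-voom, 141 without the 3 libraries, and 53 to 117 leaving out 1, with 56, 53 and 58 without sham replicates 3, 5 and 6 and 57 without 1 day replicate 5. Those the other way (86) numbered 51 to 104, with 51, 53, 57 and 56 without sham replicates 1, 2, 4 and 5.

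Replicate numbers did not pair the libraries: deviations from the group means correlated with a median of -0.012 between same-numbered libraries, only 4 of 36 pairs exceeded 0.1, and 2 of 24 libraries correlated best with their own number. With the replicate block, 1691 genes were higher and 1729 lower at 1 day, 1192 and 1214 at 3 days, and 1508 and 1560 at 12 weeks, and it changed no call of a printed gene but that of ENSRNOG00000043098 at 1 day, with a log2 fold change of 1.24 (edgeR adjusted p = 0.0338). The folds that moved are those of ENSRNOG00000043098 at 12 weeks (3.87), with a log2 fold change of 3.06 without 12 week replicate 3, 2.84 with surrogate variables, 3.24 with limma-voom and 3.23 without the 3 libraries, and of ENSRNOG00000020407 at 12 weeks (-3.96), with -4.73 without 12 week replicate 2, and at 3 days (-0.60), with -1.59 without 3 day replicate 5 or without the 3 libraries, -1.79 with limma-voom and -1.42 with surrogate variables; these 4 were called. The other 10 gained calls were 5 of ENSRNOG00000043098 at 1 day, and 3 of ENSRNOG00000021027 and 2 of ENSRNOG00000014448 at 12 weeks. On simulated counts 1.5-fold changes were recovered less often than 4-fold ones at each time (at 3 days 52.9% against 93.2%), so small changes may be missed.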

Other observations

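The direction of the calls varied with abundance. The 15065 tested genes were ranked by mean log2 CPM and divided into 4 parts. At 1 day 56.5% of the genes called in the least abundant part were higher than sham, 319 higher and 246 lower, against 43.9% in the most abundant part, 460 higher and 588 lower. At 3 days the shares were 57.9% and 45.7%. At 12 weeks the order was the other way, with 49.9% in the least and 55.6% in the most abundant part. The difference between these shares was not tested, since genes are not independent replicates. The size of the called changes fell with abundance at each of these times. At 1 day the median absolute log2 fold change was 1.09 in the least and 0.31 in the most abundant part, where smaller changes can be called.

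The 100 genes with the highest mean CPM held 49.7% of the counts on average. Among them 5 were higher and 7 lower than sham at 1 day, where 24% of all tested genes were called. At 3 days 6 were higher and 7 lower, where 17.5% of all tested genes were called, and at 12 weeks 15 and 10, where 22.1% were. Between 12 weeks and 3 days 20 were higher and 16 lower at 12 weeks, where 31.3% of all tested genes were called. The differences between these shares were not tested.

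The spread between libraries also differed between groups. The biological coefficient of variation fitted to each group alone was 0.124 in sham, 0.153 at 1 day, 0.177 at 3 days and 0.214 at 12 weeks. Without 3 day replicate 5 it was 0.155 at 3 days, and without 12 week replicates 1 and 3 it was 0.160 at 12 weeks. These removals were chosen after the libraries had been seen. The main fit shared its dispersion estimate over all groups. Fits of only the 2 groups called 4829 rather than 3615 genes at 1 day against sham, and 2869 rather than 2632 at 3 days. They called 3000 rather than 3334 at 12 weeks and 259 rather than 413 for 3 days against 1 day. For 12 weeks they called 3280 rather than 4718 against 3 days, and 4320 rather than 5106 against 1 day. Those fits also hold fewer libraries, so the part due to unequal spread was not separated.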
